A study of Homo sapiens with 4 samples.

How the data were processed

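RNA of U87 cells was measured in 4 libraries, 2 with the tRF-3009a mimic and 2 with the single-stranded luciferase control, from poly(A)-selected RNA sequenced as pairs, per the labels' protocols. The submitters' processing notes name kallisto, DESeq2 and hg38, without versions and without the annotation release. The deposited table gives a signal per Ensembl transcript, which the authors made by estimating reads per transcript and dividing them by a size factor for each library, as far as the column values show. In the low values of each library, 95.6% to 99.7% were whole multiples of 1 step within a tolerance of 0.1, and dividing by that step gave the whole reads used for edgeR and DESeq2. The lowest sum of recovered reads in a transcript row was 10, so transcripts below that were not analysed here. No sample column outside the series was used.

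Of 100809 transcripts, 90627 (89.9%) matched GENCODE v29 (GRCh38) by identifier without version, 79272 of them with the same version, and their values were summed over 22017 genes. Transcripts that did not match held 3.26% to 3.57% of each library's values and were left out. Symbols came from a gene name table and coordinates, 3' UTRs and GC content from the annotation. A gene with a shared or overlapping sequence can exchange reads with its copy when reads are split among transcripts.

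The test over genes was limma with a trend on log2(value + 1), for genes with a mean over the 4 libraries of at least 10, two-sided, with Benjamini-Hochberg adjustment at 0.05. A fold change is therefore on the log2(value + 1) scale, which understates the change of low genes. Lists were fixed before the data were examined and tested with camera at a preset correlation of 0.01 for lists with at least 5 members, with an estimated correlation and fry beside it. The labels do not give the sequence of tRF-3009a. It was taken from general knowledge as the last 18 nt of mature tRNA-Leu-TAA with its CCA end, ACCCCACTCCTGGTACCA, and the seed-site result holds only for that sequence. Sites were searched in the 3' UTR of the transcript with the highest mean of each of 12991 protein-coding genes, if it was at least 20 nt long. Median differences were tested with 100000 permutations across genes and against 10000 lists drawn, for each site gene, from the 20 nearest site-free genes in 3' UTR length, GC content and mean expression. Matched lists for gene groups were drawn from the 50 nearest genes in GC content and mean expression.

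The genes named were chosen by a rule fixed before the data were examined. It takes in each direction the 12 protein-coding genes with the largest fold changes among those past the test, with groups that do not overlap and a mean of at least 50, filled up with the smallest p-values where fewer pass. It adds the 4 members with the smallest p-values of each called list, the smallest p-value or the range of each other list, and the 6 seed-site genes with the smallest p-values that were lower in the mimic. No gene passed, so all 24 of the first part were filled up. Some genes that the rule takes are not reported here.

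The limma test over genes, camera at the preset correlation and the seed-site tests were tried on simulated data, and the other steps were not. With counts drawn for 16283 genes without a difference between numbers, 89 of 100 genes changed 2-fold and 100 of 100 changed 4-fold were recovered, with 11 false calls. With the number difference of the data, over 16316 genes, 0 of 100 and 0 of 100 were recovered by the fit without a block, and 78 of 100 and 100 of 100, with 8 false calls, by the fit with replicate number as a block. These counts had the same dispersion for every gene and no GC trend between groups. Pooling the variance across genes, as the blocked fit does, suits such counts, so its recovery and false calls need not hold for the data. A shift of -0.1 put into the seed-site genes was found as -0.085, on noise that was independent across genes and had no GC trend. Depth was 28860788 to 33848402 recovered reads per library.

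Alternatives were other pseudocounts, filters and scalings, limma voom, edgeR and DESeq2 on recovered reads, transcripts tested singly, replicate number as a block, other sites, and each library left out in turn. A lowess correction for GC content (span 0.3), camera with each list's own estimated correlation held fixed (0 where negative), the tools with a block and the alternatives for library similarity were added after the data were seen. R 4.3.3 with limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.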

Results

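Polyadenylated RNA was sequenced from U87 cells, an established human glioblastoma line, 48 h after transfection with 50 nM of an oligonucleotide. In 2 libraries the oligonucleotide mimicked tRF-3009a, a fragment from the 3' end of a transfer RNA, and in 2 control libraries it was a single strand of an siRNA against firefly luciferase. The labels number the libraries 1 and 2 in each group. Nothing in the labels says that the libraries of a group came from separate cultures, so adjusted p-values are set against the spread between these libraries. More than 2-fold differences at 3434 genes between the controls and at 3504 between the mimic libraries argue against repeats of a single RNA sample. The labels do not give the source of that spread. Whole reads recovered from the deposited values came to 30153387 in control 1, 28860788 in control 2, 33848402 in mimic 1 and 33255642 in mimic 2. Every pair of libraries that shared a group or a number differed by more than sampling noise, and each library was counted as 1 replicate.

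The libraries were first compared with each other. Libraries with the same number were more alike than libraries with the same treatment. Across the 16523 genes tested, Pearson's r of the log2 values was 0.984 between control 1 and mimic 1 and 0.987 between control 2 and mimic 2, against 0.942 between the controls and 0.941 between the mimic libraries. These are correlations across genes, which are not independent replicates. The first principal component held 78.2% of the variance and separated number 1 from number 2. Between numbers, averaged over the groups, 3192 genes differed by more than 2-fold, while 340 genes did so between groups. The cell-cycle gene MKI67 had a normalized value of 13268 in control 1 and 13035 in mimic 1, against 2003 in control 2 and 2108 in mimic 2. ASNS, which encodes asparagine synthetase, had 857 and 914 in the number 1 libraries and 18173 and 17176 in the number 2 libraries. The inflammatory chemokine gene CXCL8 had 898 and 1137 in number 1 against 45336 and 28859 in number 2. These 3 genes were chosen after their values were seen.

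**Figure D1:**
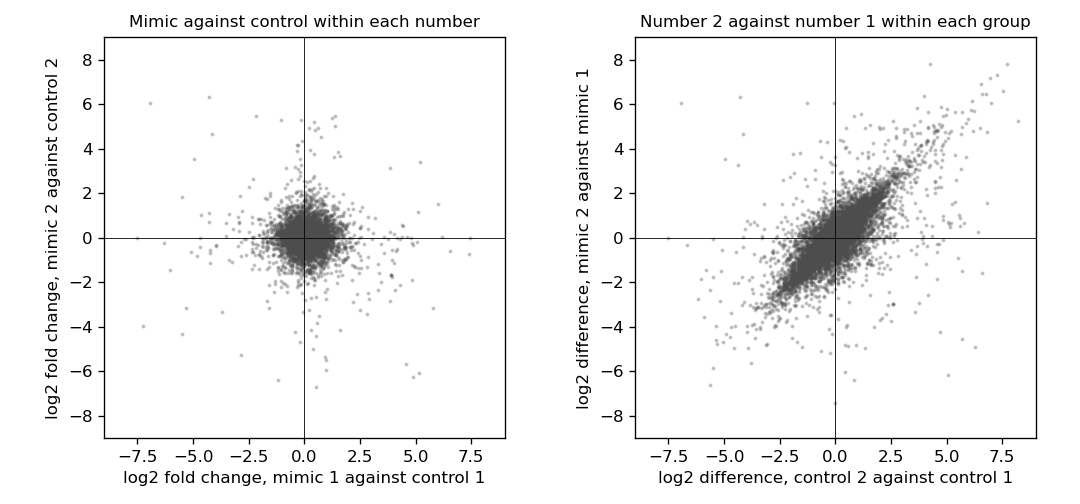
The left panel plots, for each of the 16523 genes, the log2 fold change of mimic 1 against control 1 (x axis) and of mimic 2 against control 2 (y axis). The right panel plots the log2 difference of control 2 against control 1 (x axis) and of mimic 2 against mimic 1 (y axis). The left cloud has no slope (r = -0.04), whereas the differences between numbers lie along the diagonal.

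The comparison of the mimic with the control asked which transcripts differ after the fragment is introduced. No gene passed the test, which has no term for the replicate number. Among the genes with the smallest p-values, RPS9, which encodes a protein of the small ribosomal subunit, had 1708 and 1042 in the controls and 634 and 614 in the mimic libraries, a log2 fold change of -1.10 ± 0.32 (SE, n = 2 per group). SHMT1, which encodes cytosolic serine hydroxymethyltransferase, had 628 and 353 in the controls against 283 and 114, a log2 fold change of -1.39 ± 0.59. SLCO4A1, an organic anion transporter gene, had 1895 and 2105 against 1220 and 1377, a log2 fold change of -0.62 ± 0.21. On the higher side SNX6, which encodes a sorting nexin of the retromer, had 321 and 333 in the controls and 526 and 488 in the mimic libraries, a log2 fold change of 0.63 ± 0.24. POLR3G, which encodes a subunit of RNA polymerase III, had 579 and 539 against 1154 and 736, a log2 fold change of 0.72 ± 0.31.

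Further higher genes of the rule were FAM47E-STBD1 (log2 fold change 1.37), SYNPO2 (1.73), ENSG00000283782 (0.83), SMIM11 (1.36), NME1-NME2 (0.53), RFX7 (3.13), ZNG1F (0.59), WNT3 (0.95), OR2M3 (0.85) and ENSG00000285258 (0.84). Further lower genes were ZBTB12 (-1.72), ENSG00000270149 (-1.64), SCAND1 (-0.48), ENSG00000285943 (-0.91), STS (-3.75), LAMA5 (-0.41), LPCAT2 (-0.52) and COL8A1 (-0.66). None of the 24 genes of the rule passed this test, and the smallest adjusted p over all genes was 1.00 with limma. The absence of calls holds for fits without the replicate number. With that number as a block, limma called 117 genes, edgeR 94 and DESeq2 4. Of the 46 genes named here, 22 passed with such a block. The labels do not say that same-numbered libraries are pairs, and the blocked limma fit pooled its variance across genes, so these calls stay provisional. RFX7 was at 5.19 in control 1 and 89.6 in control 2, and STS was listed at 0 in mimic 1 and at 43.0 in mimic 2, so their fold changes rest largely on a single library. With 1 library left out the groups no longer held the same numbers, so the difference between numbers entered the fold changes. Of the 24 fold changes, 12 then moved by over 1.5 times. SHMT1 ran from -2.04 to -0.73, POLR3G from 0.40 to 1.05, OR2M3 from 0.38 to 1.32, SMIM11 from 0.78 to 1.94, SYNPO2 from 1.07 to 2.38 and COL8A1 from -1.03 to -0.29. The others that moved were LAMA5, ENSG00000285943, ENSG00000270149, ENSG00000285258, RFX7 and STS. Within numbers 1 and 2, SHMT1 was at -1.15 and -1.63, with a log2 difference between numbers of -1.07, while COL8A1 was at -1.18 and -0.15. All 24 genes had the same sign within both numbers, since the rule takes only genes whose groups do not overlap. FAM47E-STBD1 and NME1-NME2 are readthrough genes that overlap their neighbours, and RPS9 has near-identical copies, so the split of reads among transcripts makes these values uncertain. ENSG00000285258 shares the symbol ATXN7 with another gene identifier, and the remaining named genes were not checked for shared sequence. RPS9 lies on chromosome 19 from 54200742 to 54249003, SHMT1 on chromosome 17 from 18327860 to 18363563, SLCO4A1 on chromosome 20 from 62642445 to 62685785, SNX6 on chromosome 14 from 34561094 to 34630183 and POLR3G on chromosome 5 from 90471748 to 90514553 (GRCh38).

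With limma, 0 genes were higher and 0 were lower at an adjusted p under 0.05, and 26 of 16523 genes had an unadjusted p under 0.05, where chance alone would give about 826. On the recovered reads edgeR and DESeq2 also called 0 genes, with 50 and 61 genes at an unadjusted p under 0.05. The smallest adjusted p with DESeq2 was 0.0584, close to the threshold. Within number 1, 741 genes differed by more than 2-fold between mimic and control, and within number 2, 633 did. Only 72 genes did so in the same direction within both numbers, and 79 did so in opposite directions. Across all genes the fold changes within number 1 and within number 2 had a Pearson's r of -0.04, and 50.0% of genes had the same sign. Of the 6199 genes with a mean value of at least 1000, 0 differed by more than 2-fold in the same direction within both numbers. On simulated counts with the number difference of these data, this test, which has no term for the number, recovered 0 of 100 genes changed 4-fold, against 100 of 100 without that difference, so a count of 0 does not exclude changes of that size.

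The fixed gene lists asked whether groups of related genes moved together. Extracellular matrix genes, immediate-early genes, mitochondrially encoded genes and replication-dependent histone genes were lower in the mimic by small amounts with camera at a preset correlation. None of these 4 calls held with an estimated correlation, where the adjusted p was 0.967 to 0.981. That test rests on few residual degrees of freedom and called no list at all, so the losses do not show that these lists did not move. The histone list was fixed as a sign of RNA quality and not as a pathway, since most of its transcripts lack a poly(A) tail, and it moved in the same direction as the other 3 lists. Of the 26 matrix genes 23 were lower, with a median log2 fold change of -0.16, and 21 were lower within both numbers. The collagen cross-linking enzyme gene LOX had a mean of 8316 ± 291 (SD, n = 2) in the mimic against 9556 ± 399 in the control, and MMP2, a gelatinase gene, had 47813 ± 672 against 54988 ± 2194. The membrane metalloprotease gene MMP14 had a log2 fold change of -0.16. Of the 19 immediate-early genes 18 were lower, with a median of -0.14. The AP-1 subunit genes FOSB, FOSL1 and JUN had log2 fold changes of -0.60, -0.24 and -0.18, and the transcription factor gene KLF2 had -0.45. With 1 library left out FOSL1 ran from -0.39 to -0.09 and KLF2 from -0.72 to -0.18. Of the 13 mitochondrially encoded genes 12 were lower, with a median of -0.14, which was -0.26 within number 1 and -0.02 within number 2. The respiratory chain genes MT-ND4L, MT-CYB, MT-ND4 and MT-ND3 had log2 fold changes of -0.25, -0.21, -0.21 and -0.17, and MT-CYB ran from -0.32 to -0.10 and MT-ND4 from -0.29 to -0.14 with 1 library left out. Of the 14 histone genes 13 were lower, with a median of -0.22, and H1-4, H4C14, H4C3 and H2BC12 had -0.76, -0.83, -0.35 and -0.20. Of the 16 list genes of the rule, 10 moved by over 1.5 times with 1 library left out. Without mimic 1, H1-4 was at -0.14, H4C14 at -0.07 and MT-ND3 at -0.0013, and H2BC12 was at -0.02 without control 1. Without mimic 2, H4C3 was at 0.0037. With a library left out the groups no longer held the same numbers, so the difference between numbers entered all these values. Within numbers 1 and 2, H1-4 was at -1.24 and -0.27, H4C14 at -1.09 and -0.57 and H2BC12 at -0.23 and -0.17. H4C3 was at 0.016 and -0.71 and MT-ND3 at -0.34 and 0.0035.

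**Figure D2:**
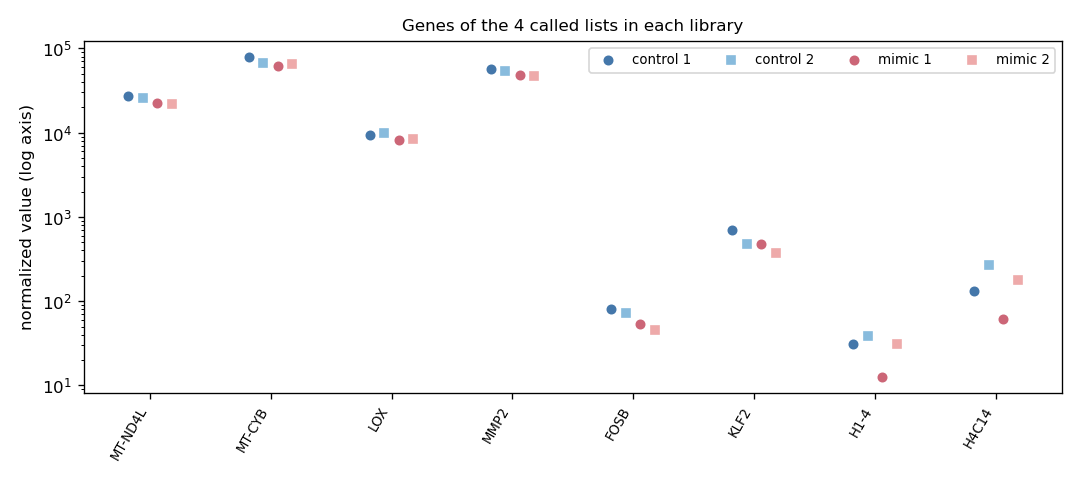
Normalized values (y axis, log scale) of the 2 genes with the smallest p-values from each of the 4 called lists (x axis), with 1 point per library. Circles are number 1 and squares number 2, in blue for the control and red for the mimic. FOSB lies at 80.0 and 71.7 in the controls and at 54.0 and 45.9 in the mimic libraries.

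Of the 26 lists tested with camera at the preset correlation, these 4 passed, at adjusted p of 0.00177 for the matrix genes, 0.00177 for the immediate-early genes, 0.00223 for the mitochondrially encoded genes and 0.0446 for the histone genes. No call held with an estimated correlation, where the adjusted p was 0.967 for the matrix genes, 0.967 for the immediate-early genes, 0.981 for the mitochondrially encoded genes and 0.981 for the histone genes. With fry every list had an adjusted p of 0.995. Both tests take the difference between numbers as residual spread and called none of the 26 lists, so they had little power here. Between numbers, camera with an estimated correlation did not call even the ATF4 and integrated stress response genes (adjusted p = 0.479). Their median log2 difference was 3.24. With a library left out, 2 of the 4 lists were still called without either control library, 1 without mimic 1 and 2 without mimic 2. The histone list turned to the higher side without control 2 and without mimic 1. The groups then no longer held the same numbers, so the difference between numbers entered. Within numbers 1 and 2 the histone median was -0.23 and -0.19, and 9 genes were lower within both, against a median of 4 in matched lists. No member of any list passed over all genes tested (0) or adjusted over the list alone (0). The histone genes were higher in number 2 by a median log2 difference of 1.26, while the difference between numbers was -0.17 for the matrix genes, 0.07 for the immediate-early genes and -0.11 for the mitochondrially encoded genes.

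The other 22 lists were not called, with adjusted p from 0.0628 to 0.975. The median log2 fold change was -0.12 for TGF-beta and YAP target genes, -0.10 for hypoxia and glycolysis genes, -0.09 for metallothionein and oxidative stress genes, -0.16 for NF-kB and cytokine genes and -0.09 for p53 target genes. It was -0.09 for G1/S genes, 0.01 for G2/M genes, -0.03 for ATF4 and integrated stress response genes, 0.04 for aminoacyl-tRNA synthetase genes and -0.01 for cytosolic ribosomal protein genes. Interferon-stimulated genes had a median of 0.03, with members from -0.32 (RSAD2) to 0.32 (IFIT2). The RNA silencing machinery had a median of 0.01, with members from -0.26 (TNRC6C) to 0.13 (PRKRA), and tRNA processing nucleases ran from -0.40 (ANG) to 0.27 (TRNT1). Endoplasmic reticulum chaperones ran from -0.15 (SDF2L1) to 0.17 (HSPA5), heat shock proteins from -0.26 (HSPB1) to 0.08 (HSPD1), cholesterol genes from -0.19 (LSS) to 0.20 (HMGCS1) and nuclear oxidative phosphorylation genes from -0.47 (NDUFA6) to 0.11 (UQCRB). Nuclear-retained and non-coding RNAs ran from -0.16 (RN7SL1) to 0.68 (RPPH1), and astrocyte and glioma genes from -0.41 (SLC1A3) to 0.53 (FABP7). Markers of other cell types ran from -0.33 (SLC17A7) to 0.14 (MAP2) for neurons, from -0.94 (ESRP1) to 0.75 (CDH1) for epithelium and from -0.42 (TEK) to 0.43 (PECAM1) for endothelium. The medians of the neuron, epithelial and endothelial markers were -0.16, -0.14 and -0.25, within or below the range of the 4 called lists. Oligodendrocyte and immune markers had 4 members each and were not tested, with medians of -0.03 and -0.18.

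The seed-site comparison asked whether transcripts that can pair with the start of the fragment were lower in the mimic. Genes with a site for positions 2 to 8 of the mimic in the 3' UTR (AGTGGGG) were lower than genes without one by a very small amount, and the difference was not present in both pairs of libraries. The 1711 site genes had a median log2 fold change of -0.03 and the 11280 site-free genes -0.02. The difference was -0.018 (100000 permutations across genes, one-sided permutation p = 2e-05), but genes are not independent replicates. With camera, which allows for correlation between genes, the site genes had p = 0.313 at the preset correlation and p = 0.421 with an estimated one. Within number 1 the difference was -0.057, and within number 2 it was 0.013, in the opposite direction. It was 0.0060 without control 2 and 0.028 without mimic 1, but there the difference between numbers entered, since the groups no longer held the same numbers. Against lists of site-free genes matched on 3' UTR length, GC content and mean expression, whose medians centred on -0.04, the site genes lay at percentile 96.6, which is not lower. The 6 site genes that were lower with the smallest p-values included SNAI1, GNAT1, MEF2B, DUSP7 and FURIN, and none of the 6 passed. With 1 library left out 3 of the 6 moved by over 1.5 times, and MEF2B ran from -1.60 to -0.38 and FURIN from -0.45 to -0.22. The epithelial-mesenchymal transition factor gene SNAI1 (chromosome 20, 49982999 to 49988886), with a site at position 630 of an 830 nt 3' UTR, had 17.7 and 24.7 in the controls and 9.90 and 7.63 in the mimic libraries. The phosphatase gene DUSP7 (chromosome 3, 52048919 to 52056550), with a site at position 1331 of a 1896 nt 3' UTR, had a log2 fold change of -0.35 ± 0.20 (SE). The proprotein convertase gene FURIN (chromosome 15, 90868592 to 90883458), with a site at position 1139 of a 1580 nt 3' UTR, had -0.33 ± 0.21.

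**Figure D3:**
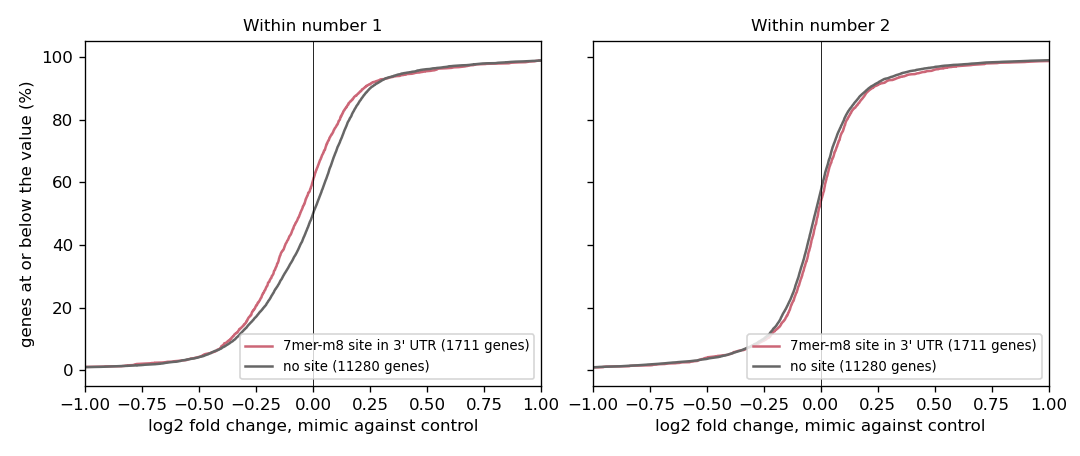
Cumulative share of genes (y axis, %) at or below each log2 fold change of mimic against control (x axis), for 1711 genes with a site in the 3' UTR (red) and 11280 without (grey), within number 1 (left) and number 2 (right). The site genes lie to the left in number 1 (difference of medians -0.057) and slightly to the right in number 2 (0.013).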

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

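The GC correction, camera with own correlations held fixed, the GC correction's combination with the replicate block, the blocked edgeR and DESeq2 fits and the alternatives for library similarity were chosen after the data were seen. The count of 0 genes was the same under the other pseudocounts, filters and scalings, limma voom, edgeR, DESeq2, single transcripts, the GC correction and each library left out. Same-numbered libraries deviated together (r = 0.745 across genes), but 2 pairs and the labels do not establish a pairing. With a replicate block limma called 117 genes (55 higher, 62 lower), edgeR 94 and DESeq2 4. The replicate block with the GC correction called 2, RPS9 and SHMT1, which were called by all of these blocked fits. In the limma fit with the block the variance was pooled across genes (16523 degrees of freedom), so its p-values do not rest on each gene's own spread. Of its 117 genes 34 had a library at 0.

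Of all 26 lists, 4 were called in the main test, 0 with an estimated correlation and 0 with fry. With a pseudocount of 8 and with a mean of at least 50, 3 were called and the histone call was lost (adjusted p 0.0527 and 0.141). With each list's own estimated correlation held fixed 2 were called, both among the 4. With the replicate block 10 were called, and 10 with the replicate block and GC correction, the 4 among them each time. With a library left out 9 to 12 were called, 2 to 6 of them higher and 1 or 2 among the 4, when the groups no longer hold the same numbers. The seed-site difference of -0.018 was -0.0078 for the 8mer site (one-sided permutation p = 0.116), -0.0034 with the GC correction (permutation p = 0.180) and reversed to 0.0066 against matched genes. It was -0.023 for the 7mer-A1 site, -0.031 for the 6mer site and -0.018 for sites in coding sequence (permutation p = 1e-05 each, the smallest they can give). It ran from -0.077 to 0.028 with a library left out, and was above 0 without control replicate 2 (0.0060) and without mimic replicate 1 (0.028). The excess of same-number over same-group correlation, 0.044, was 0.080 with a mean of at least 50. The cause was not tested for the block, the 8mer site or this filter.

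Of 868 values of the 46 named genes under alternatives, 819 kept their direction and stayed short of the threshold. The 48 that passed all had a replicate block, and H4C3 changed sign without mimic replicate 2 (0.0037; -0.70 to 0.0037 over the libraries left out). Depth limits genes near the filter, where a few reads move the fold change.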

Other observations

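The tests with a GC correction, with each list's own correlation held fixed, of direct repression and of wrong labels were chosen after the results they bear on were seen. The difference between the number 1 and number 2 libraries, present in both treatments, ran through several gene groups. Of 21 ATF4 and integrated stress response genes, which serve amino acid supply and stress signalling, 20 were more than 2-fold higher in number 2, with a median log2 difference of 3.24. The 12 of 12 further ATF4 target genes, chosen after that was seen, were higher too, with a median of 1.44. Of 22 NF-kB and cytokine genes 19 were more than 2-fold higher, with a median of 2.41, and IL6 had 262 and 212 in number 1 against 10931 and 10816 in number 2. Aminoacyl-tRNA synthetase genes had a median of 0.80 and p53 target genes 0.63, and the stress cytokine gene GDF15 differed by 4.24 on the log2 scale. Of the 14 histone genes, fixed as a sign of RNA quality, 12 were higher in number 2, 10 of them by more than 2-fold. Of 16 astrocyte and glioma genes 7 were more than 2-fold lower and 3 more than 2-fold higher, with a median of -0.48. Of 5 endothelial markers 4 were more than 2-fold lower, with a median of -1.24. Genes of cell division were lower in number 2. Of 25 G1/S genes 22 were more than 2-fold lower, with a median of -1.97, and of 28 G2/M genes 26 were, with a median of -1.85. The mitotic kinesin gene KIF20A differed by -3.77 and the carbonic anhydrase gene CA9, a marker of hypoxia, by -3.96, although of 25 hypoxia and glycolysis genes 6 were more than 2-fold lower and 3 more than 2-fold higher, with a median of -0.51. With limma and group as a term, 4609 genes were higher and 4283 lower in number 2 at an adjusted p under 0.05. Like the blocked fit, this fit pooled its variance across genes, so these p-values do not rest on each gene's own spread. With camera and an estimated correlation none of 27 lists passed between numbers, with adjusted p of 0.479 or more.

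For this difference between numbers, a trend with GC content was argued against, since the ATF4 list kept a median of 3.23 with the trend removed. Treatment labels attached to the wrong libraries stay open: the seed-site genes lay at percentile 99.0 of matched lists between numbers, but the 8mer, 7mer-A1 and 6mer sites lay at 88.1, 79.0 and 56.9, and the site's rank of 16 from the highest of 16176 words was matched by 17 between mimic and control within number 2. Genes with a site for the luciferase siRNA lay at percentile 2.78 between numbers for the sense strand (28 genes) and 6.91 for the antisense strand, towards the side that exchanged labels would give but neither below the bound of 2.5 set for such a test. Antisense-site genes were higher in the mimic than site-free genes by 0.030 (0.042 within number 1 and 0.012 within number 2, two-sided permutation p = 0.0197). Against matched lists they lay at percentile 64.6, which is not higher. Sense-site genes went the other way, with a difference of -0.065 (-0.13 within number 1 and -0.045 within number 2, two-sided permutation p = 0.0331). The luciferase sites therefore do not speak for the labels as given. Since replicate number is not a treatment in the labels, no biological explanation given by the design was tested.

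For the 4 lists that were lower in the mimic, correlated genes may account for the calls of the mitochondrially encoded and histone genes. Their adjusted p was 0.620 and 0.978 with each list's own estimated correlation held fixed in camera. That correlation came from a fit without a term for the number, so it takes in the difference between numbers, and was 0.999 for the ATF4 list. With the number as a block and the preset correlation, camera called the mitochondrially encoded and histone lists (adjusted p 0.000750 and 0.00934). The correlation held fixed therefore cannot decide the cause of these calls. For the matrix and immediate-early genes the adjusted p with the correlation held fixed was 0.0136 and 0.000854. The immediate-early estimate was negative and set to 0, below the preset value, so that this call could not be lost. A correlation held fixed also leaves out its error on 2 residual degrees of freedom, and with an estimated correlation camera gave both lists an adjusted p of 0.967 and fry gave 0.995, so correlated genes stay open there too, as does an effect of the mimic. With the GC content trend of the fold changes removed 3 lists were still called, and the histone genes ended at an adjusted p of 0.0592 although their median went from -0.22 to -0.24. The GC trend was argued against as the whole cause for the matrix genes, whose median then lay at percentile 0.02 or below of matched lists within each number. It was also argued against for the mitochondrially encoded genes within number 1, where their median was -0.26 before the removal, against 0.073 in matched lists. With the trend removed their median over both numbers went from -0.14 to -0.18, although within number 2 they lay at percentile 50. The immediate-early genes lay at 33.8 within number 1, so the GC trend stays open for them there.

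The seed-site difference was weighed against GC content and length of the 3' UTR. The 3' UTRs of site genes had a median GC content of 47.4% and length of 2471 nt, against 40.8% and 906 nt in the others, and fold changes within number 1 fell with 3' UTR GC content (Spearman's rho -0.52 across genes) but not within number 2 (rho 0.099). Against matched lists the site genes lay at percentile 96.6, which is consistent with GC content and length as the source of the difference, while genes with the 7mer-A1 site lay at 4.78. Repression through the main site (positions 2 to 8) was not found but stays open, since the site genes lay at percentile 9.06 of matched lists within number 1 and at 100 within number 2. This holds for the sequence assumed for the fragment.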
